A study of Medicago sativa with 9 samples.

How the data were processed

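Leaf lncRNAs were measured in 9 libraries of alfalfa, 3 each from control plants and from plants sprayed with selenite at 100 mg/L (low Se) or 500 mg/L (high Se). Per the labels' protocols, about 5 µg of total RNA with an integrity number above 7 was depleted of ribosomal RNA, fragmented and reverse-transcribed, with dUTP in the second strand, which keeps the strand of the RNA. The submitters' processing notes name HISAT2, Bowtie2, StringTie and edgeR, with no role or version. The genome build and annotation are not given in the sources used here. Coordinates are those of the deposited table, which names 32 chromosomes (1.1 to 8.4) and numbered scaffolds.

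The deposited table gives FPKM per transcript and library, that is fragments scaled by transcript length and by the mapped fragments of the library, per the file headers. It also gives the mean coverage per base, a signal not scaled for depth, per the file headers. The authors listed the value 0.0001 in place of 0 in both, and it was set back to 0. Columns of deposited scores named CPC and CNCI give coding potential; all CPC values are at most 0.493 and all CNCI values are below 0, so the table holds only transcripts predicted to be non-coding. Other deposited columns give transcript length, the number of exons, strand, position, a class code and the name of a host gene. The class codes u, i, j, o and x were read in the sense used for StringTie assemblies, as intergenic, intronic, spliced sharing a junction, sense-overlapping and antisense. 71.0% of the transcripts carry no strand, so that reads of overlapping genes on either strand cannot be assigned for these.

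Within each library FPKM was a constant multiple of coverage, to within 0.00015%. If FPKM follows StringTie's usual formula, the ratio gives the aligned bases, 1.44 to 2.97 gigabases per library. Coverage multiplied by length clustered at multiples of 141 bases, taken as the read length, which gave estimated reads per transcript. Coverage multiplied by length was a whole number, within 0.02 bases, for 51.0% to 57.5% of the values of a library; the rest hold bases divided between transcripts or positions. As the table holds no counts, no count test was run and no counting interval is given. The median tested transcript had 1.54 to 7.60 estimated reads per library, which limits the precision of single values. Copies of a gene on the homologous chromosomes, and paralogs, can share reads, and single transcripts are uncertain for that reason.

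All 9 libraries entered 1 fit. Values were tested as log2(FPKM + 0.1) with limma 3.58.1 in R 4.3.3, with a variance trend, for transcripts with a mean of at least 0.5 FPKM over the 9 libraries (43763 of 64684). A transcript was called at a Benjamini-Hochberg adjusted p below 0.05, in each of the 3 pairwise comparisons and in the moderated F test of any difference. Fold changes and their standard errors are on the log2(FPKM + 0.1) scale. The overlap of the 2 comparisons against control was set beside 200 simulations of unchanged groups with 1 shared control group, all 9 libraries drawn anew. Transcript classes were tested with Fisher's exact test, with camera at a preset correlation of 0.01 and at an estimated one, and with fry. Class means per library were compared with an exact permutation test, two-sided.

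Transcripts named in the text follow a rule fixed before the data were examined: in each pairwise comparison, up to 10 rising and 10 falling transcripts with the largest change among those with an adjusted p below 0.05, a mean of at least 1 FPKM in the higher group and groups that do not overlap; where fewer than 5 met this in a direction, those with the smallest p up to 5, said not to pass; and the 5 transcripts with the highest mean. Designs, the main test and the alternatives were also fixed then. Gene lists for sulfur and selenium metabolism, phosphate and ABC transport, glutathione, reactive oxygen, photosynthesis, heat shock and hormones, and markers of other organs and cell types, had been fixed too. None has a measured member: the table lists only predicted lncRNAs, its host gene names match no identifier of the gene table at hand (assembly Bolivia_mono), and no annotation of the host genes was used here. For the same reason the function of the host genes is not given.

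The test was checked on simulated data: values of the 43763 transcripts with 200 changed by known folds, 5 runs, for high Se versus control. It recovered 0% of 4-fold, 1.6% of 16-fold, 16.8% of 64-fold and 42.8% of 256-fold changes, with a mean of 2.4 false calls among 33. At this spread only very large changes can pass.

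Alternatives covered the pseudocount, the filter, 2 other scalings, the variance model, weights for libraries, the samples in the fit, the replicate number as a block, each library left out and a lenient threshold. Other tests and the figures used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.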

Results

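Long non-coding RNAs (lncRNAs, transcripts of at least 200 bases with no predicted coding potential) were profiled in leaves of field-grown alfalfa, cultivar Kangsai. Plants 20 cm tall were assigned to 3 groups and sprayed 3 times, once every 7 days. The low Se group received selenite at 100 mg/L and the high Se group at 500 mg/L, and the labels do not state what the control group was sprayed with. The series description speaks of 3 selenite concentrations, so whether control is a dose of 0 is not certain. Selenite is an inorganic form of selenium that plants take up and assimilate in part through phosphate and sulfur pathways. Each group held 3 libraries of rRNA-depleted total RNA. Nothing in the labels says that the 3 libraries of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical.

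The deposited table listed 64684 predicted lncRNA transcripts from 61864 loci. Intergenic transcripts made up 69.3% of them, intronic ones 22.1%, spliced transcripts sharing a junction with an annotated gene 4.24%, sense-overlapping ones 2.52% and antisense ones 1.88%. Their median length was 313 bases, 79.0% had a single exon and 71.0% carried no strand. The ratio of coverage to FPKM implied 1.44 to 2.97 gigabases of aligned sequence per library, of which 11.8% to 15.6% fell on the listed transcripts. Few reads stood behind a typical transcript: the median over the 43763 tested transcripts was 1.54 to 7.60 estimated reads per library. The number of transcripts above 0 was 30050 ± 4221 in control, 30800 ± 2675 in low Se and 35090 ± 1791 in high Se (mean ± SD, n = 3 each). Control 3 had 2.78 aligned gigabases and 26121 detected transcripts, fewer than in any other library.

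**Figure D1:**
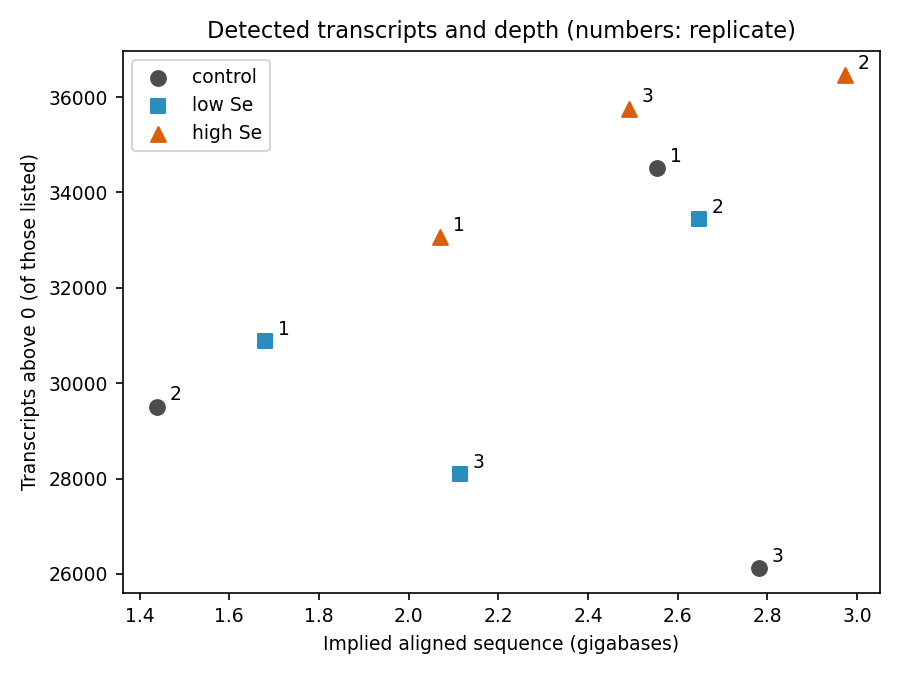
Number of listed transcripts above 0 FPKM in each library (vertical axis) against implied aligned gigabases (horizontal axis); each point is a library, and its number is the replicate. Control 3 lies lowest, at 26121 transcripts with 2.78 gigabases, and high Se 2 highest, at 36455 with 2.97 gigabases.

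The abundant end of the table was held by a few short transcripts. MSTRG.91972.1, a 303-base antisense transcript of 2 exons on chromosome 5.1 (71793729 to 71794712, minus strand, host gene MS.gene038092), had 76550 ± 10220 FPKM in control, 77280 ± 16890 in low Se and 62850 ± 11190 in high Se (mean ± SD, n = 3). Next came the sense-overlapping MSTRG.100870.1 on chromosome 5.3, with 30500 ± 14350, 37770 ± 3251 and 33800 ± 4625 FPKM in the same order, then MSTRG.91972.2, a second form at the locus of the first. MSTRG.105411.1, an intergenic transcript of 327 bases on chromosome 5.4, had 16250 ± 2243 FPKM in control, 21920 ± 3695 in low Se and 14000 ± 2890 in high Se. None of the 5 most abundant transcripts passed the test for any difference among the groups, with limma adjusted p from 0.675 to 0.999. The fifth of them, MSTRG.21071.1 (303 bases, chromosome 1.3), was listed at 0 in control 3, low Se 1 and high Se 2 and at 6008 to 16780 FPKM in the other 6 libraries. The cause of such zeros stays open, so transcripts are said to be listed at 0, and a called transcript with such a value in part of a group is given per library. The 10 highest transcripts took 49.9% to 62.6% of the FPKM of a library.

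Libraries of a group resembled each other only moderately more than libraries of different groups. Across the tested transcripts, which are not independent replicates, Pearson's r of log2(FPKM + 0.1) averaged 0.357 over the 9 pairs within groups (0.259 to 0.459) and 0.282 over the 27 pairs between groups (0.227 to 0.318). The 3 high Se libraries correlated at 0.390 to 0.459, low Se 2 with low Se 3 at 0.435 and control 2 with control 3 at 0.394. Control 1 correlated with its group at 0.260 and 0.259, below its 0.271 to 0.301 with the selenite libraries. Low Se 1 correlated with its group at 0.303 and 0.307, levels also seen between groups. The first 2 principal components held 17.75% and 14.95% of the variance. On the third, with 13.53%, control 1 scored 406.5 and every other library between -95.74 and 26.15.

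**Figure D2:**
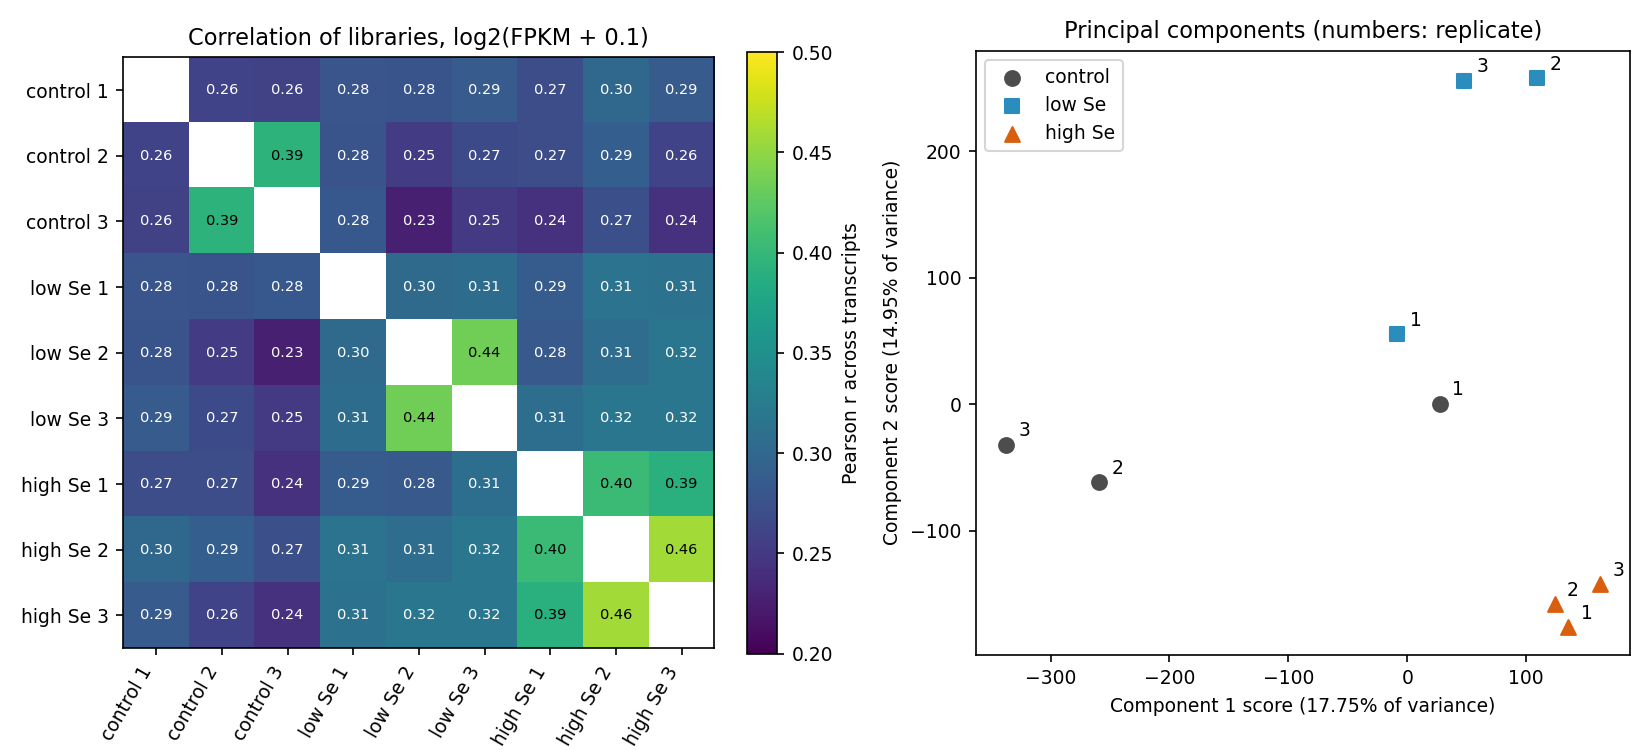
Left, Pearson's r between the 9 libraries across the tested transcripts on the log2(FPKM + 0.1) scale; right, scores on the first 2 principal components, with 17.75% and 14.95% of the variance, symbols for groups and numbers for replicates. The 3 high Se libraries lie together, while control 1 and low Se 1 lie between the groups on these 2 components. On the third component, not drawn, control 1 lies far from all others.

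The first comparison asked which leaf lncRNAs differed at the lower dose. Low Se leaves differed from control in 12 of 43763 tested transcripts, of which 5 rose and 7 fell. The intergenic MSTRG.515.1 on scaffold 15132 (67110 to 68221, a single exon of 1112 bases without strand) fell from 121, 158 and 284 FPKM in the control libraries to a listing of 0 in all 3 low Se libraries (limma adjusted p = 0.00018). The other 6 that fell were also listed at 0 in every low Se library and at 3.06 to 15.9 FPKM in each control library. They were the intergenic MSTRG.69891.1, MSTRG.129749.1, MSTRG.100041.2, MSTRG.131912.1 and MSTRG.4787.1 and the antisense MSTRG.112200.1, whose host gene is MS.gene05222. MSTRG.100041.2, with 7 exons on chromosome 5.3 (56577912 to 56580462, plus strand), had 7.66, 6.28 and 7.19 FPKM in control. All 7 were above 0 in every high Se library.

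Among the 5 that rose in low Se, MSTRG.91813.1, a transcript of 415 bases within an intron of MS.gene47024 (chromosome 5.1, 69642576 to 69642990, minus strand), had 0.373, 0.0871 and 0 FPKM in control against 143, 16.04 and 14.6 in low Se. Its change was 7.29 ± 0.89 (SE) on the log2(FPKM + 0.1) scale, which understates changes of low values, with a limma adjusted p of 0.00576. The intergenic MSTRG.15485.1 (chromosome 1.2, 73612197 to 73612695) and MSTRG.69946.1 (chromosome 4.1, 49415291 to 49416438) were listed at 0 in all control libraries. MSTRG.15485.1 had 13.4, 14.7 and 18.6 FPKM in low Se, and MSTRG.69946.1 had 78.3, 30.7 and 34.0. MSTRG.15771.1, which shares a splice junction with MS.gene34399, rose from 0.0918, 1.207 and 0 to 19.4, 19.5 and 10.7 FPKM, and the intergenic MSTRG.157031.1 rose from 0.828, 0 and 0 to 7.01, 30.8 and 28.1 FPKM. An unadjusted p under 0.05 was reached by 3688 transcripts, where uniform p-values would give 2188. These 6 libraries can be split 3 against 3 in 10 ways. At least 12 calls came from 3 of these splits, the real one included, and the highest other gave 19. The count of 12 is thus not beyond that of arbitrary groups. Leaving out 1 library moved the count of 12 to between 2 and 30: to 28 without control 1 (15 rose, 13 fell), 30 without low Se 1 (6 rose, 24 fell), 5 without control 2 (4 rose, 1 fell), 3 without control 3 (2 rose, 1 fell), 3 without low Se 2 (1 rose, 2 fell), 4 without high Se 1 (2 rose, 2 fell) and 2 without high Se 2 (1 rose, 1 fell). It was 19 with a pseudocount of 1 (12 rose, 7 fell), 56 without the filter (28 rose, 28 fell), 6 with a mean of at least 2 FPKM (2 rose, 4 fell) and 1, which fell, without the variance trend or in a fit of the 6 samples alone, so the balance of directions depends on these choices. With 1 library left out, MSTRG.515.1 passed in each of the 9 fits, while the others were lost in 2 to 9 of them. In a fit without both control 3 and low Se 3, chosen after seeing the data, none of the 12 passed, MSTRG.515.1 included.

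The higher dose was compared with control in the same way. High Se leaves differed from control in 10 transcripts, of which 8 rose and 2 fell. The largest change on the log2(FPKM + 0.1) scale was in MSTRG.91813.1 (10.04 ± 0.89 SE, limma adjusted p = 0.000204). It had 420, 103 and 239 FPKM in high Se against 0.373, 0.0871 and 0 in control. On that scale the size of a change from a listing of 0 depends on the 0.1 added. Another 4 were above 0 in high Se alone: MSTRG.86040.1, MSTRG.10405.1, MSTRG.7326.1 and MSTRG.75431.2 were listed at 0 in all control and all low Se libraries. MSTRG.7326.1, antisense to MS.gene063265 (chromosome 1.1, 26140924 to 26231671, 2 exons, minus strand), had 28.6, 18.6 and 20.99 FPKM in high Se, and the spliced intergenic MSTRG.75431.2 (chromosome 4.2, 49300766 to 49302082, plus strand) had 25.5, 17.7 and 22.9. The single-exon intergenic MSTRG.86040.1 (chromosome 4.4, 42325466 to 42325969) and MSTRG.10405.1 (chromosome 1.1, 75834544 to 75834823) had 12.7, 34.3 and 83.5 and 20.6, 18.8 and 43.2 FPKM. The remaining 3 that rose were MSTRG.124945.1, MSTRG.15485.1 and MSTRG.15771.1. The intergenic MSTRG.124945.1 had 0.6111, 0 and 0 FPKM in control and 20.14, 18.02 and 92.36 in high Se (limma adjusted p = 0.0431).

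Both transcripts that fell at the higher dose were at most 0.848 FPKM in each high Se library. MSTRG.515.1 had 0.848, 0.149 and 0.102 FPKM (limma adjusted p = 0.00131 against control). The sense-overlapping MSTRG.136627.1 (3 exons, chromosome 7.4, 37028538 to 37629718, host gene MS.gene055020) had 38.4, 16.3 and 7.25 FPKM in control and 0.276, 0.476 and 0 in high Se (limma adjusted p = 0.0442). Its exons hold only 350 bases of this long interval, and its junctions were not checked. MSTRG.136627.1 was lost in all 9 fits with 1 library left out and MSTRG.515.1 in 2 of them. The next 3 by p, which did not pass, were the intergenic MSTRG.74879.1, MSTRG.16786.1 and MSTRG.89296.1, listed at 0 in every high Se library, with limma adjusted p of 0.0622, 0.0646 and 0.0661. An unadjusted p under 0.05 was reached by 4051 transcripts. Of the 10 splits of these 6 libraries, 2 gave at least 10 calls, the real one included, with a highest other of 10. With 1 library left out the count of 10 changed, and rises no longer outnumbered falls without low Se 2 or any 1 high Se library. The count became 30 without control 1 (21 rose, 9 fell), 3 without control 2, which all rose, and 1 without control 3, which rose. Without low Se 2 it was 2 (1 rose, 1 fell) and without low Se 3 it was 4 (3 rose, 1 fell). Without high Se 1 it was 1, which fell, without high Se 2 it was 3 (1 rose, 2 fell) and without high Se 3 it was 2 (1 rose, 1 fell). It was 36 with a pseudocount of 1 (29 rose, 7 fell), 49 without the filter (39 rose, 10 fell), 26 with weights for libraries (21 rose, 5 fell), 6 without the variance trend (5 rose, 1 fell), 4 with the replicate block, 2 with a mean of at least 2 FPKM and 1 with a pseudocount of 0.01 or in a fit of the 6 samples alone. Across all tested transcripts the median log2 change was 0.26, or 0.17 after median-of-ratios rescaling and 0.04 after quantile normalization, so small rises lie within the general shift.

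A direct comparison of the doses asked which transcripts differed between 500 and 100 mg/L. 9 transcripts passed, of which 8 were higher and 1 lower in high Se. All 8 were listed at 0 in every low Se library. They comprised the 4 transcripts above 0 in high Se alone and 4 that were also above 0 in every control library. Of the latter, MSTRG.131912.1, an intergenic transcript of 259 bases on chromosome 7.3 (44910876 to 44911134, minus strand), had 7.45, 5.62 and 8.19 FPKM in control and 31.8, 21.3 and 9.48 in high Se (limma adjusted p = 0.0059 against low Se). MSTRG.40373.1, antisense to MS.gene89082 on chromosome 2.4, had 0.522, 4.16 and 19.1 FPKM in control and 19.9, 22.1 and 26.6 in high Se. The antisense MSTRG.112200.1 and the intergenic MSTRG.4787.1 had 7.80 ± 4.43 and 6.14 ± 2.83 FPKM in control and 7.85 ± 3.15 and 8.30 ± 3.00 in high Se (mean ± SD, n = 3). The 1 lower transcript, the intergenic MSTRG.130637.1 (chromosome 7.3, 23915702 to 23916828), had 39.1, 46.3 and 46.4 FPKM in low Se, 0.117, 0 and 0 in high Se and 5.998, 0.174 and 0 in control (limma adjusted p = 0.0442 for high Se against low Se).

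Of the falling transcripts that did not pass between the doses, MSTRG.136627.1 had a limma adjusted p of 0.0882, as had MSTRG.72199.1, and MSTRG.16786.1 and MSTRG.89296.1 had 0.157 and 0.159. An unadjusted p under 0.05 was reached by 3430 transcripts. The count of 9 became 14 without control 1, 23 without low Se 1, 1 without control 2, 1 without control 3, 2 without low Se 2, 3 without low Se 3 and 0 without any 1 of the 3 high Se libraries. It was 22 with a pseudocount of 1 (17 higher, 5 lower), 23 without the filter (18 higher, 5 lower), 20 with weights for libraries (17 higher, 3 lower), 4 in a fit of the 6 samples alone, 2 with the replicate block, 1 with a pseudocount of 0.01 or a mean of at least 2 FPKM and 0 in limma without the variance trend, where 4029 transcripts had an unadjusted p under 0.05.

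**Figure D3:**
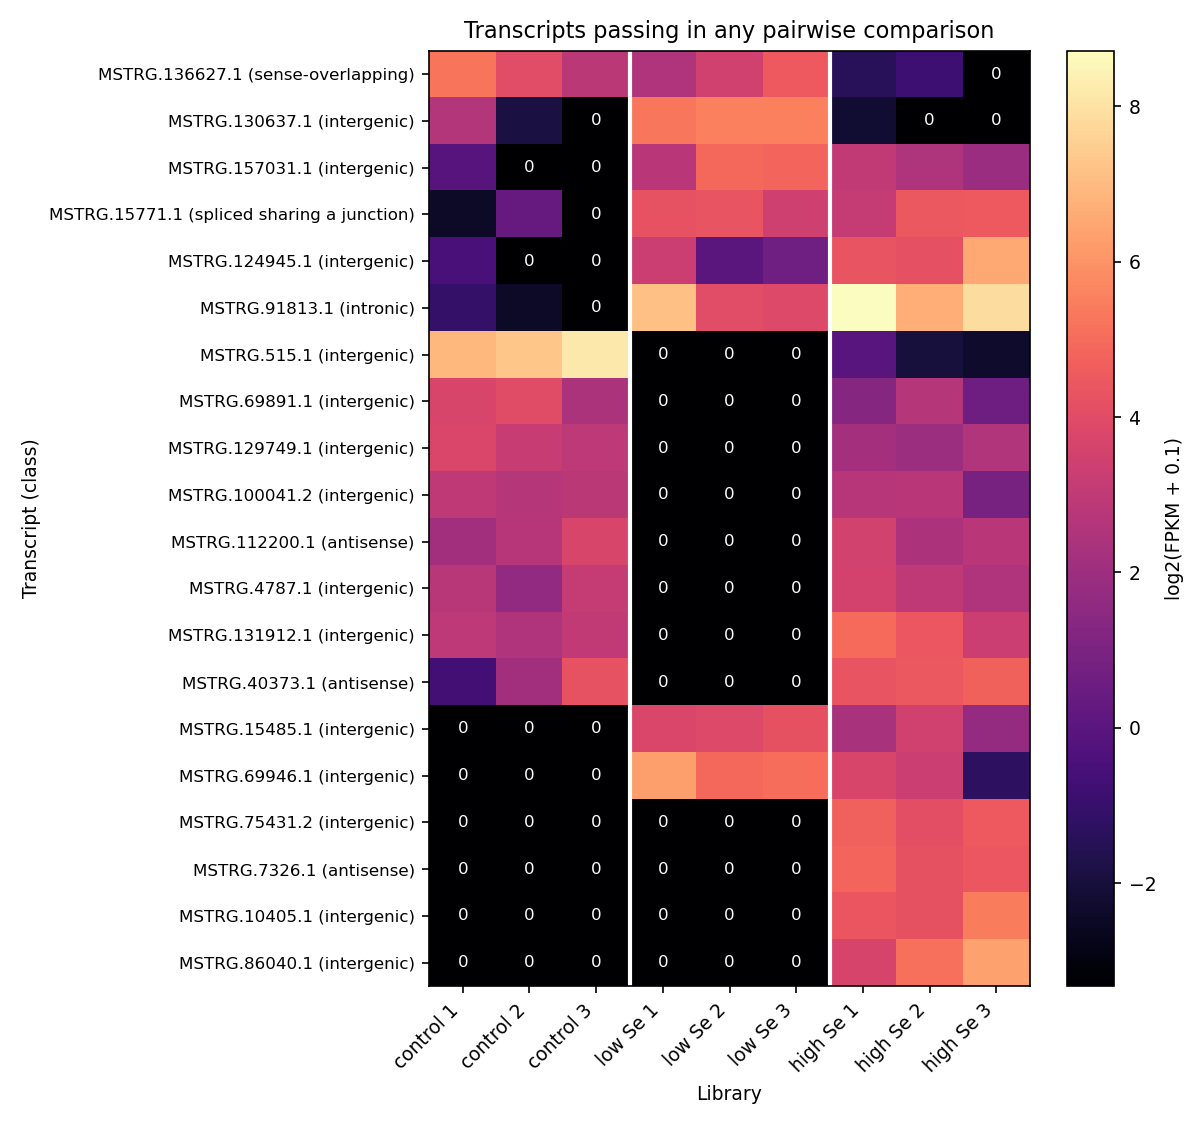
Level of the 20 transcripts that passed in any pairwise comparison (rows, with class) in each of the 9 libraries (columns); colour gives log2(FPKM + 0.1) and a white 0 marks a value listed at 0. Low Se libraries are at 0 for 12 of the 20 transcripts and control libraries for 6, and no row is at 0 in all 3 high Se libraries.

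Taking the 20 transcripts of the 3 comparisons together, 14 were intergenic, 13 had a single exon and 10 carried no strand. 14 were listed at 0 in every library of at least 1 group, for which no fold change is given. Testing for any difference among the 3 groups called 19 transcripts, 18 of them among these 20. Of the 19, 9 were listed at 0 in every low Se library and above 0 in each of the other 6, 4 were listed at 0 in every control and low Se library and above 0 in each high Se library, 2 (MSTRG.91813.1 and MSTRG.15771.1) passed against control at both doses with their highest mean in high Se, though not between the doses, 3 were highest in low Se and 1 had means that fell with dose. The transcript called only by this test, MSTRG.10145.1, which shares a junction with MS.gene006292, was named after its values were seen. It had 4.79, 4.80 and 4.90 FPKM in control, 0 in each low Se library and 4.58, 3.76 and 6.98 in high Se (limma adjusted p = 0.0433). The count of 19 became 37 without control 1, 35 without low Se 1, 12 without control 2, 5 without control 3, 4 without low Se 2, 1 without high Se 1, 3 without high Se 2 and 7 without high Se 3. It was 66 with a pseudocount of 1, 8 with a pseudocount of 0.01, 108 without the filter, 6 with a mean of at least 2 FPKM, 5 without the variance trend and 47 with weights for libraries.

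Against control, 4 transcripts passed at both doses, in the same direction at each dose. MSTRG.91813.1, MSTRG.15485.1 and MSTRG.15771.1 rose and MSTRG.515.1 fell. In the 9 fits with 1 library left out, MSTRG.515.1 was lost in 0 at low Se and 2 at high Se. In the same order, MSTRG.91813.1 was lost in 4 and 1, MSTRG.15485.1 in 2 and 8 and MSTRG.15771.1 in 8 and 8. MSTRG.15771.1 had similar levels at the 2 doses, 16.55 ± 5.03 and 17.7 ± 7.76 FPKM (mean ± SD, n = 3). In 200 simulations of unchanged groups with 1 shared control, the doses shared 0 calls, but each comparison then had at most 2 calls, so that 0 is no measure of chance for lists of 12 and 10. Independent lists of these sizes would share 0.000914 rising and 0.00032 falling calls. Across transcripts the 2 sets of log2 changes correlated at r = 0.536, against 0.4999 in the simulations, with a covariance of 1.84 against 1.27. The simulations drew transcripts independently, each with 1 spread for all groups. Shifts shared by the transcripts of a library, and a wider spread in control, were not simulated. These differences from the simulations are therefore no measure of a response common to the doses. Since 3 control libraries cannot be split into sets of at least 2, part of the excess over independent lists may come from the shared controls.

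Antisense transcripts were over-represented among the calls between the doses: 3 of the 9 were antisense, all 3 higher in high Se, while 994 of the 43763 tested transcripts were (Fisher's exact p = 0.000886, two-sided, 0.00443 after adjustment over the 5 classes). They were MSTRG.40373.1, MSTRG.7326.1 and MSTRG.112200.1, of 254, 282 and 312 bases. Each has 2 exons and an intron far longer than these, and the junctions were not checked. All 3 were listed at 0 in every low Se library. In the same order their means were 7.91, 0 and 7.80 FPKM in control and 22.9, 22.7 and 7.85 in high Se. Fisher's exact test took no account of level. 459 of the 994 antisense transcripts had a mean of at least 2 FPKM, against 10205 of all 43763. All 9 calls had a mean of at least 4.81 FPKM, so part of the excess may follow from level. No other class passed this test in any comparison, and no class as a whole passed camera or adjusted fry. The adjusted p of Fisher's exact test for antisense calls was 0.0326 with a pseudocount of 1 (22 called). It was 0.0179 without control 1 (14 called), 0.0372 without low Se 1 (23 called) and 0.225 with the replicate block (2 called). It was 0.333 without low Se 3 (3 called) and 1 without low Se 2 (2 called). With a pseudocount of 1 intronic (0 called) and sense-overlapping (3 called) transcripts passed Fisher's exact test too, at adjusted p of 0.0221 and 0.0472. Without low Se 1 the intronic class (0 called) also passed it, at 0.0234, and in low Se versus control (1 called) at 0.0383. Without control 1 the antisense class also passed Fisher's exact test against control. It held 5 of 28 calls at low Se (adjusted p 0.00195) and 4 of 30 at high Se (adjusted p 0.0231). In that fit the excess was not particular to the comparison between the doses. Without control 2 or control 3, or with a mean of at least 2 FPKM, 1 transcript was called, and without high Se 1, high Se 2 or high Se 3 none was, too few to test the share.

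Antisense transcripts (994 tested) had a mean log2(FPKM + 0.1) of 0.44 ± 0.08 in high Se, -0.12 ± 0.39 in low Se and -0.13 ± 0.29 in control (mean ± SD of library means, n = 3). Sense-overlapping transcripts (1335 tested) had 0.42 ± 0.11 in high Se, 0.00 ± 0.27 in low Se and -0.21 ± 0.37 in control. For both classes every high Se library lay above every control library, with an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 libraries can give. Intergenic transcripts had -0.53 ± 0.06 in high Se and -0.81 ± 0.27 in control, and intronic ones -0.50 ± 0.05 and -0.78 ± 0.37, with exact permutation p of 0.2 and 0.4. The share of tested transcripts above 0 moved with these means: it was 77.3% ± 1.93 in high Se and 65.3% ± 5.29 in control for antisense transcripts, and 67.7% ± 2.54 and 58.9% ± 6.63 for all transcripts (mean ± SD, n = 3).

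Against other transcripts, camera gave the antisense class an adjusted p of 0.417 for high Se versus control with the preset correlation and 0.966 with an estimated correlation, and the sense-overlapping class the same 2 values. Fry, which asks whether a class moves one way on balance, gave p of 0.0414 and 0.0359 for these classes, both 0.103 after adjustment over the 5 classes. At an unadjusted p under 0.05 in high Se versus control, 116 antisense transcripts were higher and 38 lower, against 2672 higher and 1379 lower over all tested transcripts, and 1 antisense transcript passed the adjusted test.

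**Figure D4:**
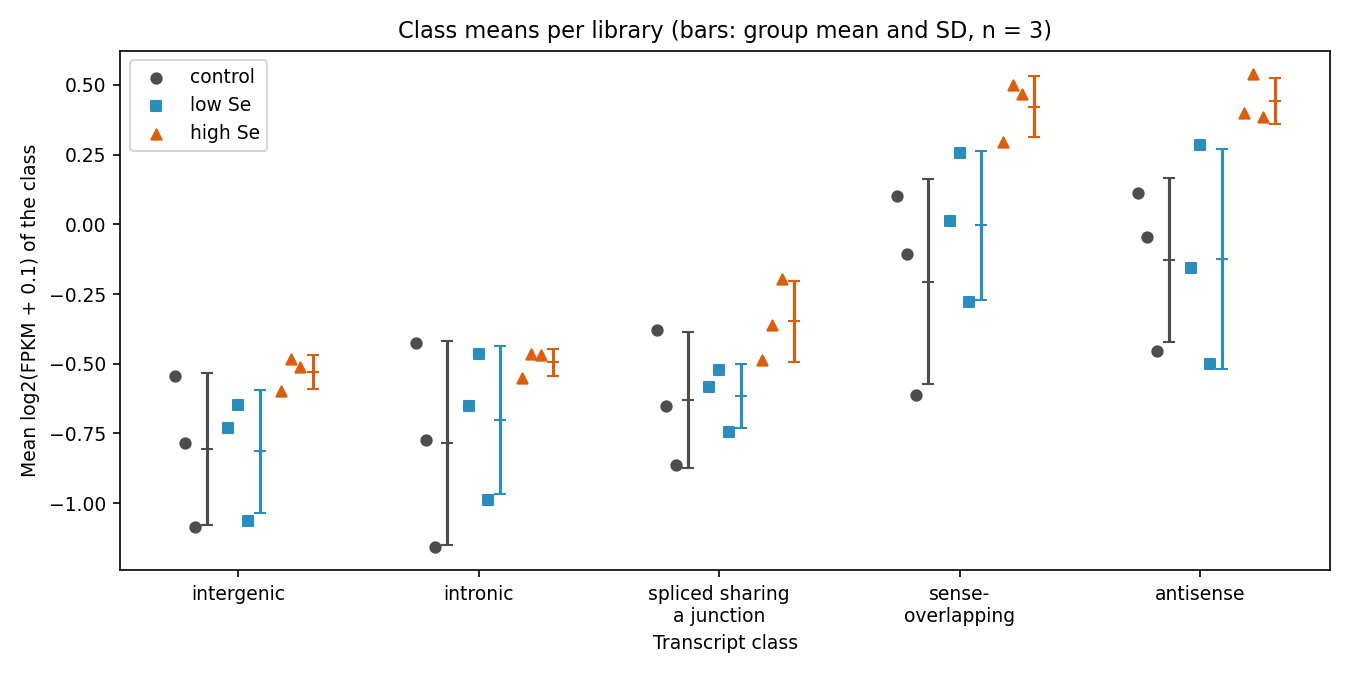
Mean log2(FPKM + 0.1) of each transcript class (horizontal axis) in each library; points are libraries, and bars give the mean and SD of the 3 libraries of a group. High Se libraries average 0.44 for antisense and 0.42 for sense-overlapping transcripts, above control averages of -0.13 and -0.21.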

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

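The alternatives were chosen before the data were examined, except the 2 fits on 7 libraries, which were chosen after seeing the data. Counts are given in the order low Se versus control, high Se versus control, high Se versus low Se and any difference, where the reported counts are 12, 10, 9 and 19. Median-of-ratios rescaling gave 13, 9, 9 and 20 and quantile normalization 10, 10, 10 and 26, all within 1.5 times. A pseudocount of 1 gave 19, 36, 22 and 66, of which 7, 9, 7 and 16 were among the reported calls. With a pseudocount of 0.01 the counts were 9, 1, 1 and 8. Testing every transcript above 0 gave 56, 49, 23 and 108, which held all of the reported calls, and a mean of at least 2 FPKM gave 6, 2, 1 and 6. Without the variance trend 1, 6, 0 and 5 passed in limma; for the 0, 4029 transcripts had an unadjusted p under 0.05. With weights for libraries the counts were 9, 26, 20 and 47. Fits on only the 6 samples compared gave 1, 1 and 4, and an unadjusted p under 0.05 with a 2-fold change 3688, 4050 and 3430. Dropping control 1 and low Se 1, which stand apart, gave 9, 23, 12 and 28. Of these only 2, 6, 2 and 7 were among the reported calls. Dropping control 3 and low Se 3, which detect the fewest transcripts, gave 2, 2, 1 and 2, of which 0, 1, 0 and 0 were. Similar counts thus hide lists that differ in most members. The cause of these shifts was not tested. With each library left out in turn the counts ranged over 2 to 30, 1 to 30, 0 to 23 and 1 to 37. The values of 0 for high Se versus low Se came from leaving out high Se 1, high Se 2 or high Se 3; without control 1 the counts were 28, 30, 14 and 37, and without low Se 1 they were 30, 12, 23 and 35.

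With the replicate number as a block the counts were 10, 4, 2 and 15. Deviations from the group means of same-numbered libraries correlated at -0.0302 to 0.00147, and those of other pairs at -0.0296 to 0.0346. These values show no pairing by number. With few reads per transcript they could miss a weak one, so a plot or day shared by same-numbered samples is not excluded. The overlap of 4 transcripts between the doses became 6 with a pseudocount of 1, 3 with median-of-ratios rescaling, 2 with a mean of at least 2 and 2 with the block. No class passed camera under any of these settings or with an estimated correlation. The 1 class whose share of calls passed Fisher's exact test (antisense, high Se versus low Se) became 3 results with a pseudocount of 1, 1 with median-of-ratios rescaling and 0 with a mean of at least 2 or with the block, where 1 and 2 transcripts were called between the doses, and 0 to 3 with 1 library left out, where 0 to 23 were; fits with 0 or 1 called could not test it. Of the 31 passing results for named transcripts, 1 (MSTRG.515.1, low Se versus control, highest adjusted p 0.0296) passed in every fit with 1 library left out, and MSTRG.91813.1 in high Se versus control was lost in 1 fit (adjusted p 0.0522). None of the 38 results that the naming rule gave for pairwise comparisons changed direction. The settings run were a pseudocount of 1, median-of-ratios rescaling, the block and 1 library left out. This is no sign of stability, because in all 38 the compared groups do not overlap. A pseudocount or a library left out then cannot reverse the direction, and the block leaves the log2 change as it was. Other alternatives, MSTRG.10145.1 and the 5 most abundant transcripts were not run. Alternatives for count data were not run, since the table holds no counts, and those for gene lists were not run, since no list had a measured member. The median tested transcript had 1.54 to 7.60 estimated reads per library, and how much of the spread between libraries comes from this depth was not tested. At the observed spread, the simulation of high Se versus control recovered 0% of 4-fold changes.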

Other observations

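The test of sets of 3 libraries listed at 0 was written before its result was seen; the other tests below were chosen after the result, or a closely related one, had been seen.

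Intronic lncRNAs of 1 host gene moved together. Over 3075 pairs of intronic transcripts from 1599 host genes, the log2 changes of high Se versus control correlated at r = 0.260 across pairs, which are not independent, against at most 0.0582 in 1000 shuffles of the hosts, which ignore position. At 1 to 10 kb apart r was 0.238 for 1880 pairs of 1 host and -0.0138 for 320 pairs of other hosts (95% bootstrap interval of the difference 0.150 to 0.377), although over transcripts of any class with a mean of at least 2 FPKM the deviations from the group means correlated at 0.262 between neighbours of other loci and hosts at that distance, so local effects on single libraries are not excluded. One hypothesis is that such transcripts are parts of 1 unspliced precursor; the test does not separate this from separate RNAs with a shared control, so r = 0.260 may reflect either. Among the 20 transcripts with the highest mean, 12 lay on chromosomes 5.1 to 5.4 and together the 20 held 59.5% of all FPKM. Of the 20, 8 had a length within the 290 to 318 bases of the 66 genes for signal recognition particle RNA, an abundant non-coding RNA that targets proteins to membranes, in the gene table at hand. Because their length is what drew attention to these transcripts, and 3 of the 8 are forms of 1 locus, the 8 do not support that source, which stays open without their sequences.

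For each of the 84 possible sets of 3 libraries, being listed at 0 in the set and holding at least 5 estimated reads in each of the other 6 libraries was met by 34 transcripts for control (rank 6 of 84), 28 for low Se (rank 7) and 11 for high Se (rank 39), against a median of 10 over the other 81 sets and a highest of 75 (control 2, control 3 and low Se 1). The test written before asked for all 3 groups among the top 4 and 0 were, which by its own bound counts against treatment. After the result was seen that bound was judged wrong and a comparison with the median of 10 added, above which control and low Se lie. That median is not matched for detection. Control and low Se held 90141 and 92414 detected transcripts in total, the set with 75 held 86506 and high Se 105278. The ranks thus give no support for zeros that follow the treatment, and leave that open. In the other direction high Se ranked 1 of 84, with 132 transcripts that held at least 5 estimated reads in each high Se library and were listed at 0 in the other 6. More detected transcripts in those libraries may contribute in part: of the 4 other sets with the highest totals of detected transcripts, 2 of them above the total of high Se, control 1, high Se 2 and high Se 3 had 86, while the others had 65, 55 and 42, each under 0.5 times the 132. A response to the higher dose and a likeness of these 3 libraries for other reasons, technical ones included, stay open.

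Well-covered transcripts were often listed at 0 in 1 library. Where both other libraries of the group held at least 20 estimated reads, 8.57% of 44406 values were at 0 (exact 95% interval 8.31% to 8.83%, which takes values as independent), and of 7279 values with at least 100 reads 4.26% were. Independent sampling of reads predicts 2.11e-05%, so it is argued against as the cause, though duplicated reads were not tested. Division of reads between near-identical copies was not settled. Where both group mates had whole base totals, 9.05% of 8887 values were at 0, so such zeros also occur without divided bases in the mates. That share was 1.07 times that of the other values (95% bootstrap interval 0.983 to 1.16). Coverage was not matched between these 2 sets of values, and the share at 0 falls with reads, so the ratio does not decide the question. A first version of this test, replaced because it favoured transcripts with zeros, gave 1.52. Reads placed whole on 1 of several copies also leave whole totals, so the test cannot address them and they stay open. Haplotype differences, if the libraries came from different plants of this outcrossing species, may account for part: among transcripts with such zeros, deviations from the group mean correlated at r = 0.170 between 475 pairs of neighbours 10 to 100 kb apart, against at most 0.0759 in 200 shuffles, and at 0.0243 from 100 to 500 kb, but transcripts from 1 longer unit would give this too, and genotypes were not tested.

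Control 1 and low Se 1 stood apart from their groups. A swap with a library of another group is argued against, since their highest r with another group was 0.315, below the 0.390 of the lowest of the 5 other pairs within groups; a single wrong label or an exchange with an outside sample needs no partner and stays open. Low depth is argued against as well, because the gap to their group mates did not shrink among the 1242 transcripts with a mean of at least 10 FPKM: it was 1.31 times that over all tested transcripts for control 1 (95% bootstrap interval 0.705 to 1.83) and 1.42 times for low Se 1 (0.898 to 2.10). Differences between plants or in sample handling within a group were not tested.

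Other splits of the libraries were refitted to ask whether the counts exceed those of arbitrary groups. For 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. In low Se versus control, 3 of the 10 splits, the real one included, gave at least the real count of 12, and the highest other gave 19; in high Se versus control 2 did, with a highest other of 10 equal to the real count; in high Se versus low Se only the real split gave 9, and the highest other gave 3. For any difference among the 3 groups, 3 of 100 splits drawn from 280, the real one included, gave at least 19, with a highest other of 26; this is under 0.05 among the splits drawn, but for all 280 the 95% interval of the share is 1.07% to 6.43%, so chance is not firmly excluded. Both larger splits put control 1 with low Se 1 and control 2 and control 3 with low Se 2.

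Control 3 detected fewer transcripts than each of the 7 libraries with fewer aligned bases, and low Se 3 fewer than each of the 3 libraries with fewer. In control 3, 57.2% of spliced and 46.4% of unspliced strandless tested transcripts were above 0, against 69.3% and 60.6% in control 1 and 62.7% and 53.7% in control 2.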
